A study of Rattus norvegicus with 6 samples.

How the data were processed

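RNA was measured in 6 rat liver samples, 3 from the vehicle group and 3 from the ginkgetin group, and the values were read from 1 table of genes by samples. Libraries were made from total RNA with a SMARTER mRNA kit, per the labels' protocols. The genome build was mRatBN7.2, per the submitters' processing notes. The aligner, the counting tool, the annotation and the strand setting are not given in the sources used here, so reads of overlapping or antisense genes and of near-identical family members cannot be told apart here.

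The deposited values are a signal, a normalized read count per gene that is 0 or above, and the deposited table does not name its normalization. In each library 99.67% of the values were whole multiples of the smallest positive value within 0.02, so each value was a number of reads divided by 1 factor per library. The factors recovered in this way differ by at most 0.35% from median-of-ratios size factors recomputed from the reads. The exceptions were 53 of 16209 rows, in 3 runs of neighbouring genes that carry a constant offset of under 1 read, and these were rounded for tests on reads. Of the row names, 23 had been turned into dates, as spreadsheets do, and none of these is named in the text. Symbols of 14544 rows were found in a RefSeq gene table of another rat assembly, GRCr8, 739 more as synonyms, and 926 in neither. That table was used for names only, and no coordinates are given because its assembly is not the one named above.

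Columns named for ginkgetin were matched to the ginkgetin samples by name and number. The other 3 columns carry the letters TAA, which are not in the labels. They were taken as vehicle replicates 1 to 3 because the series has only the vehicle group besides, and every direction in the text rests on this assignment. The labels call the samples replicates and do not say that each came from a separate animal, so p-values measure the spread between these samples. No pair of libraries was a duplicate: the chi-square of their reads per degree of freedom was at least 53.3. Samples were grouped by the labels, and groups, tests, the 30 gene lists and most alternative settings were fixed before the data were examined. The 3 gene groups under other observations were chosen afterwards.

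Because the values are normalized, the main test was limma 3.58.1 in R 4.3.3, with a mean-variance trend and robust moderation, on log2(value + 1), for genes with a value of at least 1 in 3 or more libraries. The test for raw counts that had been laid down as the other branch of the design was run on the recovered reads as an added alternative. Adjusted p values are Benjamini-Hochberg values over the 14639 genes tested, at 0.05. The 30 gene lists were tested with limma's camera, two-sided, with a preset correlation of 0.01 and adjustment over the lists, and again with an estimated correlation and with fry, a self-contained set test. Members were counted over all genes and adjusted over the list alone. Counts over the list alone with a library left out or in another setting take higher and lower members together. List means and library totals were compared by exact two-sided permutation tests, whose smallest p for 3 against 3 is 0.1. Bootstrap intervals of list medians resampled the genes of a list, which vary together, and not libraries, so they do not measure spread between samples. A group at 0 reads was set to a floor of 3 reads per library, which covers counting error only. For named genes with 1 to 3 reads over the ginkgetin libraries, the ratio of pooled reads is given with an exact conditional interval, over all libraries and without the vehicle library with the most reads.

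Named genes were chosen by a rule, from genes past 0.05 with a gene symbol, no overlap between groups and a mean above the median of the tested genes. It took the 10 with the largest rise and the 10 with the largest fall, or all if fewer passed. Where fewer than 5 passed in a direction, it took the 5 with the smallest p in that direction. In addition up to 4 members with the smallest p per list were eligible, and Col1a1, Col3a1, Acta2, Tgfb1 and Timp1 always.

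Reads assigned to genes ranged from 13372367 to 14933853 per library. The sum of normalized reads was 15863575, 11768875 and 8265117 in vehicle replicates 1 to 3 and 16510702, 16250451 and 16991873 with ginkgetin. The share of reads from 13 mitochondrial genes was 15.3%, 11.0% and 6.3% with vehicle and 19.7%, 4.2% and 7.5% with ginkgetin. The procedure was tested on simulated reads for this comparison with 200 of 14639 genes changed. At the spread of these libraries (common dispersion 0.184) it recovered 6% of genes changed by 1 log2 unit, 71% at 2 and 92% at 3. These were 3 of 50, 71 of 100 and 46 of 50 genes, beside 14 false calls among 14439 unchanged genes. The share of false calls among all calls was therefore above the threshold of 0.05 in this simulation. Camera called 0 of 30 unchanged lists. Reads were simulated independently for each gene, so that 0 does not bear on false list calls in these libraries, where other groupings called 9 to 19 lists.

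Alternatives set down beforehand were pseudocounts of 0.1 and 0.5, no filter and a filter at 5, TMM and quantile scaling, the replicate number as a block, leaving out each library, sample weights, a fold threshold of 2 and an unadjusted p. Chosen after the data were examined were equal library totals, moderation without robust settings, a threshold of 0.10 and tests on recovered reads with edgeR 4.0.16, DESeq2 1.42.0 and limma-voom. Figures were drawn with matplotlib 3.10.9.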

Results

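Bulk RNA sequencing measured gene expression in 6 liver samples from rats with liver fibrosis, 3 given vehicle and 3 given ginkgetin, a plant biflavone, at 10 mg/kg/day. The reads assigned to genes numbered 13372367, 14150827 and 13465287 in vehicle replicates 1 to 3. They numbered 14933853, 14045519 and 13735802 in ginkgetin replicates 1 to 3. Values are normalized read counts, and fold changes are differences of log2(value + 1) between ginkgetin and vehicle, which understate the change of genes with few reads. The comparison asks what ginkgetin treatment does to the transcriptome of the fibrotic liver.

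Vehicle replicate 3 stood apart from the other libraries. Alb, which encodes albumin, the main secreted protein of hepatocytes, took 2.89% of its reads, against 9.44% and 7.77% in vehicle replicates 1 and 2. The share was 6.56%, 12.11% and 10.89% in ginkgetin replicates 1 to 3. Hepatocyte markers lay at a median of -2.17 on the log2 scale relative to the mean of the other vehicle libraries (bootstrap 95% interval -2.56 to -1.89, 22 genes). Collagen and matrix genes lay at 2.37 (1.75 to 2.89, 35 genes). The first principal component held 58.7% of the variance and placed this library at -141.3, vehicle replicates 1 and 2 at -1.5 and -50.5, and the ginkgetin libraries at 38.9, 71.3 and 83.2. Vehicle replicate 1 had a Spearman correlation across genes of 0.974 with vehicle replicate 2, 0.972 with ginkgetin replicate 1 and 0.909 with vehicle replicate 3, where genes are not independent replicates.

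Matrix, bile duct and proliferation genes had lower means in the ginkgetin livers, and genes of hepatocyte metabolism had higher means. Of 35 tested genes for collagens and extracellular matrix, 33 had lower means with ginkgetin, at a median log2 fold change of -2.17. All 16 cholangiocyte and ductular markers and all 32 cell cycle genes had lower means, at medians of -2.38 and -2.20. Hepatocyte markers (22 of 22 higher, median 1.18) and genes of fatty acid oxidation (24 of 26 higher, median 1.44) lay on the other side, at 0.34 and 0.68 without vehicle replicate 3. The matrix median was -1.27 without that library. Camera with an estimated correlation called 0 of 30 lists. Of 14639 genes tested with limma, 2 passed a Benjamini-Hochberg threshold of 0.05, 1 higher and 1 lower. At an unadjusted p of 0.05 there were 2963, of which 1025 were higher and 1938 lower, where chance gives 732 on average. The split was 1117 and 1397 with quantile scaling and 347 and 2924 with equal library totals. The 3 values of one group did not overlap the 3 of the other in 4017 genes, 27.4% of those tested, where chance gives 10% on average. Genes vary together, so a single grouping can lie far from both averages. Other groupings of the 6 libraries gave 82 to 1388 genes at an unadjusted p of 0.05. Their share of genes without overlap was not counted.

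Cd276, which encodes the immune checkpoint protein B7-H3, fell by 3.09 on the log2 scale (SE 0.287, adjusted p = 0.0314, limma), from 433, 552 and 654 normalized reads in the vehicle livers to 81.8, 55.5 and 53.2 with ginkgetin. The locus LOC367746, named here after its values were seen, was at 0 reads in the 3 vehicle libraries and at 227, 83.3 and 191 normalized reads with ginkgetin, at least 63.4-fold higher against a floor of 3 reads per library (adjusted p = 0.0225, limma). Neither passed in limma when vehicle replicate 2 or any one ginkgetin replicate was left out, where 0 genes passed and 1745 to 2808 had an unadjusted p under 0.05. Without vehicle replicate 1 the count was 696, and without vehicle replicate 3 it was 84. On whole reads recovered from the values, edgeR called 0 genes, with 2469 at an unadjusted p of 0.05, and DESeq2 called 1339.

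Named genes with the smallest p on the higher side did not pass the threshold. They included Nlrp12 (log2 fold change 2.86, SE 0.427), a member of the NOD-like receptor family, and Ecm1 (2.17, SE 0.357), which encodes a secreted matrix protein. The others were Hamp (2.98, SE 0.489), which encodes the iron hormone hepcidin, Cela1 (2.0, SE 0.337), an elastase gene, and Aen (1.16, SE 0.204), a nuclease gene. Their limma adjusted p ranged from 0.0668 for Nlrp12 to 0.0744 for Aen. Hamp stood at 1777, 2030 and 1045 normalized reads in the vehicle livers and at 17395, 15695 and 6767 with ginkgetin. On the lower side, Fhl2 (-3.32, SE 0.398), Neurl3 (-2.49, SE 0.359), Epcam (-1.88, SE 0.275) and Car2 (-2.82, SE 0.429) each had an adjusted p of 0.0668.

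The collagen and matrix list fell (camera, a competitive gene set test, with a preset correlation of 0.01, adjusted p = 2.7e-10, and adjusted p = 0.51 with an estimated correlation). No member passed over all genes, and 23 of 35 fell when adjusted over the list alone. Col1a1, the main chain of type I collagen, had 1459, 2473 and 32623 normalized reads with vehicle and 458, 294 and 157 with ginkgetin (log2 fold change -4.14, SE 1.04, limma adjusted p over all genes = 0.111). Col3a1 had 7747, 8338 and 76088 against 3132, 4527 and 2164 (-2.44, SE 0.875, adjusted p = 0.185). The smallest p values of the list belonged to Ltbp2 (-3.07), which binds to elastic fibres, Loxl1 (-4.45), a crosslinking enzyme of elastin, Eln (-3.61), elastin itself, and Fbn1 (-2.30), a microfibril protein. The list's mean level was 1.03 ± 1.49 (SD, n = 3) with vehicle and -1.03 ± 0.55 (SD, n = 3) with ginkgetin, in log2 units centred over the 6 libraries. That difference had an exact two-sided permutation p of 0.1, the smallest that 3 against 3 libraries can give. Without vehicle replicate 3 the log2 fold changes were -2.78 for Col1a1, -1.36 for Col3a1, -3.65 for Loxl1 and -2.99 for Eln. Vehicle replicate 3 lay at 2.72, and without it the median was -1.27 and the list was still called, with 21 genes past over the list alone. Without ginkgetin replicates 1, 2 and 3 that count was 9, 6 and 3.

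Matrix proteases and their inhibitors fell as a list (17 of 19 lower, median -1.56, camera adjusted p = 7.9e-05, and adjusted p = 0.51 with an estimated correlation). Over all genes 0 passed in limma, and 7 fell when adjusted over the list alone. Among them were Mmp12 (-4.83), macrophage elastase, Mmp2 (-2.79), a gelatinase, Adamts2 (-2.72), a procollagen protease, and Timp1 (-2.60, SE 0.699), an inhibitor of matrix proteases. Without vehicle replicate 3 these were -3.82 for Mmp12, -2.06 for Mmp2, -2.20 for Adamts2 and -1.70 for Timp1. The median was -0.93 without vehicle replicate 3, and the count over the list alone was 3 without ginkgetin replicate 2 and 4 without ginkgetin replicate 3. TGF-beta signalling genes also fell as a list (15 of 23 lower, median -0.44, camera adjusted p = 0.025, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone 7 fell, and over all genes 0 passed. The 7 included Pmepa1 (-2.79) and Ctgf (-2.29), which are induced by TGF-beta, Ltbp1 (-1.82), a latent TGF-beta binding protein, Tgfb2 (-1.98) and Tgfb1 (-1.60, SE 0.507, and -1.03 without vehicle replicate 3). The call was lost without ginkgetin replicate 1 (adjusted p = 0.059) and without ginkgetin replicate 3 (adjusted p = 0.077, median -0.22). The count over the list alone was 11 without vehicle replicate 1 and 3 without vehicle replicate 2 or ginkgetin replicate 3.

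Stellate cell and myofibroblast markers were not called as a list (13 of 22 lower, median -0.66, camera adjusted p = 0.46). Acta2, the smooth muscle actin of myofibroblasts, had 67.6, 137 and 1128 normalized reads with vehicle and 255, 213 and 94.0 with ginkgetin (log2 fold change -0.35, SE 0.932, limma adjusted p = 0.851), and 0.83 without vehicle replicate 3. Adjusted over the list alone, 4 members passed, against 0 over all genes. Cygb (-3.50, and -2.82 without vehicle replicate 3), a stellate cell globin, and the platelet-derived growth factor receptors Pdgfrb (-2.49) and Pdgfra (-1.36) were lower, and Ecm1 (2.17) was higher. Without vehicle replicate 3 the list median was 0.53, without vehicle replicate 1 it was -1.23 with 7 members past, and without ginkgetin replicate 3 it was -0.33.

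**Figure D1:**
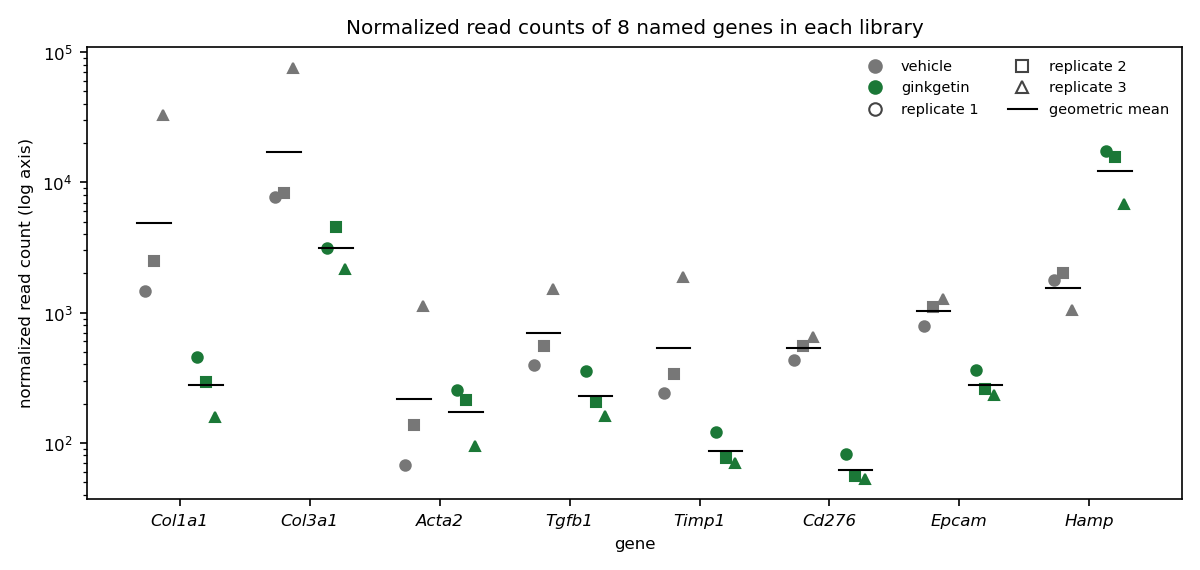
Normalized read counts of 8 named genes in each library on a log axis, vehicle in grey and ginkgetin in green, with marker shapes for replicates 1 to 3 and lines for the geometric means. Vehicle replicate 3 had 32623 reads of Col1a1 and 1128 of Acta2, against 2473 and 137 in vehicle replicate 2, whereas the vehicle values of Cd276 lay between 433 and 654.

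Cholangiocyte and ductular markers gave the smallest adjusted p of the lists together with the cell cycle genes (camera adjusted p = 1.8e-11, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 15 of 16 fell, and 0 passed over all genes in limma. The smallest p values belonged to Sctr (-3.21), the secretin receptor of bile duct cells, Cftr (-3.45), their chloride channel, Epcam (-1.88), an epithelial adhesion protein, and Cldn4 (-4.04, and -3.38 without vehicle replicate 3), a tight junction protein. Epcam had 783, 1106 and 1277 normalized reads with vehicle and 365, 259 and 233 with ginkgetin. The list's level was 1.32 ± 0.60 (SD, n = 3) with vehicle and -1.32 ± 0.52 (SD, n = 3) with ginkgetin, with an exact permutation p of 0.1, the smallest possible. With any one library left out, 14 to 16 members passed over the list alone and the median stayed between -2.75 and -2.09.

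Cell cycle genes fell as a list (32 of 32 lower, median -2.20, camera adjusted p = 1.8e-11, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone, 23 of 32 fell, and 0 passed over all genes in limma. Mki67, the Ki-67 proliferation marker, stood at 172, 515 and 693 normalized reads with vehicle and at 66.3, 39.3 and 139 with ginkgetin (-2.45, SE 0.607). Ccna2 (-2.75), which encodes cyclin A2, Bub1b (-3.03), a spindle checkpoint kinase, and Mcm3 (-2.39), a subunit of the replicative helicase, were also among the 23. With 1 library left out the values ran from -3.05 to -2.03 for Mki67, -3.43 to -2.18 for Ccna2, -3.73 to -2.43 for Bub1b and -3.0 to -1.71 for Mcm3. The list's level in vehicle replicate 1, at -0.21, lay close to that of ginkgetin replicate 3, at -0.37. Over the list alone 0 genes passed without vehicle replicate 2 or 3 or ginkgetin replicate 1 or 2, although camera still called the list in each case.

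Among immune cell lists, neutrophil markers fell (10 of 10 lower, median -1.99, camera adjusted p = 0.00058, and adjusted p = 0.51 with an estimated correlation). S100a8 (-2.33, and -1.65 without vehicle replicate 3), a calcium-binding protein of granulocytes, Mpo, myeloperoxidase, Camp, an antimicrobial peptide, and Elane, neutrophil elastase, were among the 5 that fell when adjusted over the list alone. Over all genes 0 passed. Elane was at 1.19, 13.3 and 8.59 normalized reads with vehicle and at 0 in the ginkgetin libraries, at least 2.20-fold lower. That bound rests most on vehicle replicate 2. The list median was -1.75 with this gene at its bound. Mpo was at 3.56, 22.5 and 4.91 normalized reads with vehicle and Camp at 3.56, 35.8 and 6.75, so most of their reads came from vehicle replicate 2. Mpo had 38 reads over the vehicle libraries and 1 over the ginkgetin libraries, a ratio of 26.7 after scaling (exact 95% counting interval 4.50 to 1080), and 11.5 without vehicle replicate 2 (1.67 to 494). Camp had 57 and 2, a ratio of 20 (5.29 to 169), and 7.30 without that library (1.68 to 66.2). These intervals cover counting error only. Without vehicle replicate 2 or 3 or any one ginkgetin replicate, 0 members passed over the list alone. MHC class II genes fell as a list (10 of 10 lower, median -0.95, camera adjusted p = 0.0032, and adjusted p = 0.51 with an estimated correlation). In limma 0 members passed over the list alone or over all genes, and over the list alone 7 passed without vehicle replicate 3 and 2 without ginkgetin replicate 1. RT1-Bb (-1.10), RT1-Db1 (-1.13) and the class II transactivator Ciita (-1.24) had the smallest p values, and reads of the RT1 genes may be shared between near-identical family members.

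Macrophage and Kupffer cell markers were not called (12 of 19 lower, median -0.46, camera adjusted p = 0.35), and 3 fell when adjusted over the list alone, against 0 over all genes. Trem2 and Gpnmb (-4.45), markers of lipid- and scar-associated macrophages, and Cd9 (-3.19), a tetraspanin found on the same cells, were these 3. Trem2 had 67.6, 102 and 1924 normalized reads with vehicle and 3.32, 0 and 0 with ginkgetin, a ratio of 775 over 3 reads (exact 95% counting interval 265 to 3760), and 75.6 without vehicle replicate 3 (25.5 to 370). Gpnmb had 380, 729 and 16728 against 80.7, 93.7 and 56.9, and lay at -2.78 without vehicle replicate 3. Cd9 ran from -3.81 to -2.60 with 1 library left out. Timd4, a marker of resident Kupffer cells, was at 2.09 (SE 0.663) and did not pass. It had 1.19, 0.832 and 3.07 normalized reads with vehicle and 7.74, 16.2 and 7.42 with ginkgetin. The size of this change therefore depends on the 1 added before taking logs. The macrophage list was called lower without vehicle replicate 2 (adjusted p = 0.024, median -0.78) and had a median of 0.04 without vehicle replicate 3. Its count over the list alone, in either direction, was 7 without vehicle replicate 1, 5 without vehicle replicate 3 and 0 without ginkgetin replicate 2. Lymphocyte markers (median -0.39, camera adjusted p = 0.35) and endothelial markers (median -0.05, adjusted p = 0.94) were not called, with 0 members past over the list alone. With 1 library left out the medians ran from -0.61 to -0.16 and from -0.27 to 0.13. For endothelial markers the count was 8 without vehicle replicate 1, 2 without ginkgetin replicate 1 and 7 with equal library totals. Cytokines, chemokines and NF-kB genes were not called either (median -0.56, adjusted p = 0.27), with 2 members past over the list alone. These were Relb (-1.57), an NF-kB subunit, and Ccl20, a chemokine at 0 in the ginkgetin libraries and at least 4.85-fold lower. Their count was 7 without vehicle replicate 1 and 3 without vehicle replicate 3 or ginkgetin replicate 2. It was 1 without vehicle replicate 2 or ginkgetin replicate 3, and the median ran from -0.86 to -0.33 with 1 library left out.

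Hepatocyte markers rose as a list (22 of 22 higher, median 1.18, camera adjusted p = 0.00081, and adjusted p = 0.63 with an estimated correlation), although 0 members passed over the list alone or over all genes in limma. Apoa2 (1.86), a high-density lipoprotein component, Otc (1.71), a urea cycle enzyme, and the asialoglycoprotein receptor subunits Asgr1 (1.20) and Asgr2 (1.18) had the smallest p values. Without vehicle replicate 3 they lay at 1.33, 1.12, 0.59 and 0.57. The list's level was 0.45, -0.05 and -2.13 in vehicle replicates 1 to 3 and 0.34, 0.60 and 0.79 in the ginkgetin replicates, so vehicle replicate 1 lay within the ginkgetin range. Without vehicle replicate 3 the median was 0.34 (camera adjusted p = 0.03), and with quantile scaling it was 0.59 and the call was lost (adjusted p = 0.13). Periportal hepatocyte genes (12 of 13 higher, median 1.30, camera adjusted p = 0.0038, and adjusted p = 0.53 with an estimated correlation) were called higher. Genes of gluconeogenesis and amino acid catabolism (16 of 17 higher, median 1.24, camera adjusted p = 0.0017, and adjusted p = 0.63 with an estimated correlation) were also called higher. Both calls were lost without vehicle replicate 3, at medians of 0.18 (adjusted p = 0.09) and 0.04 (adjusted p = 0.47), and with sample weights (adjusted p = 0.082 and 0.14). The periportal call was also lost with quantile scaling (adjusted p = 0.13), and without vehicle replicate 1 the medians were 1.98 and 1.88. Cyp2f4 (2.35) had the smallest p of the periportal list, and Hal (2.33), histidine ammonia-lyase, that of the gluconeogenesis and amino acid list. Cyp2f4 lay at 1.40 and Hal at 1.28 without vehicle replicate 3. In both lists 0 members passed over the list alone in limma. Without vehicle replicate 1 there were 3 past in each, and without vehicle replicate 3 there were 5 periportal genes and 3 of gluconeogenesis and amino acid catabolism. Pericentral hepatocyte genes were not called (median 0.80, camera adjusted p = 0.22), with Cyp1a2 at 2.61 (1.51 without vehicle replicate 3). They were called without vehicle replicate 1 (adjusted p = 0.014), without ginkgetin replicate 2 and with equal library totals (adjusted p = 0.023 in both), whereas without vehicle replicate 3 the median was 0.12 (adjusted p = 0.50). The count over the list alone was 0, against 3 without vehicle replicate 1 and 1 without vehicle replicate 3.

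**Figure D2:**
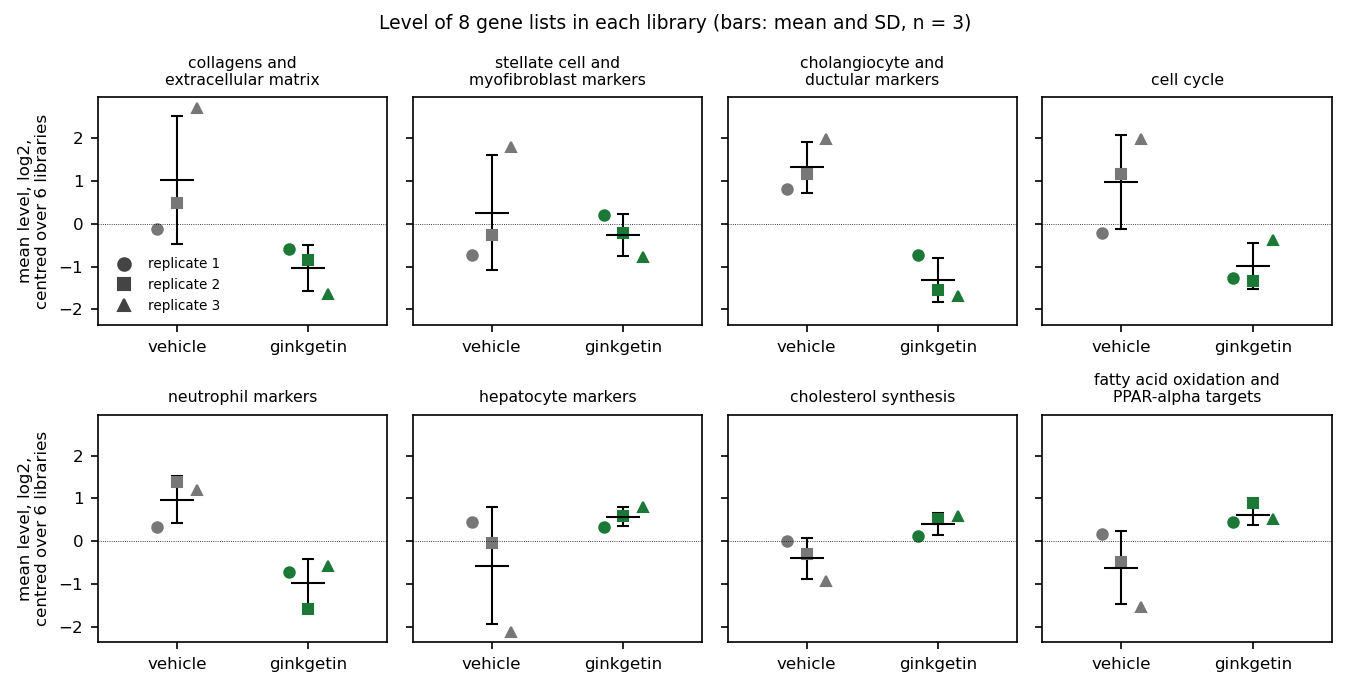
Mean log2 level of 8 gene lists in each library, centred over the 6 libraries, with bars for the mean and SD of each group (n = 3). Vehicle replicate 3 lay at 2.72 for the collagen and matrix list and at -2.13 for hepatocyte markers, and the cholangiocyte levels ran from 0.81 to 1.99 with vehicle and from -1.68 to -0.73 with ginkgetin.

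As lists, lipid and drug metabolism genes had higher mean levels with ginkgetin. Levels overlapped between groups for lipogenesis (0.05 in vehicle replicate 1 and -0.06 in ginkgetin replicate 1). They also overlapped for cytochromes P450 (0.51 and 0.31 in the same libraries). Fatty acid oxidation genes and PPAR-alpha targets rose as a list (median 1.44, camera adjusted p = 6.2e-08, and adjusted p = 0.51 with an estimated correlation). Angptl4 (1.63), an inhibitor of lipoprotein lipase, and Fgf21 (1.83), a hepatic hormone, were the 2 that rose when adjusted over the list alone. Cholesterol synthesis genes rose as a list (22 of 24 higher, median 0.89, camera adjusted p = 6.3e-08, and adjusted p = 0.51 with an estimated correlation). Adjusted over the list alone 8 rose, among them Dhcr7 (1.13), Fdps (1.03), Idi1 (1.10) and Fdft1 (0.96), enzymes of the pathway. Bile acid synthesis and transport genes rose as a list (17 of 20 higher, median 1.35, camera adjusted p = 6.2e-05, and adjusted p = 0.51 with an estimated correlation). Over that list alone 7 rose, including Hsd3b7 (1.48), an enzyme of bile acid synthesis, Nr0b2 (1.89), a nuclear receptor that represses it, and Abcc2 (2.52), a canalicular export pump, and 1 fell, the basolateral export pump Abcc3 (-1.79). Lipogenesis genes rose as a list (18 of 19 higher, median 1.01, camera adjusted p = 5.3e-05, and adjusted p = 0.51 with an estimated correlation), and the desaturases Fads1 (2.06) and Fads2 (2.72) were the 2 past over the list alone. Cytochrome P450 and xenobiotic metabolism genes rose as a list (29 of 34 higher, median 1.45, camera adjusted p = 8.1e-06, and adjusted p = 0.53 with an estimated correlation) with 0 members past over the list alone. In it Nr1i3 (1.81), a xenobiotic-sensing receptor, and Cyp3a9 (1.76) had higher values, Ces2c (-3.28) and Cyp1b1 (-3.60) had lower ones, and close paralogs may share reads. In these 5 lists 0 members passed over all genes in limma, and with quantile scaling 0 passed over the list alone. For cholesterol synthesis the count over the list alone was also 0 with TMM scaling. With a pseudocount of 0.1 it was 4 for cholesterol synthesis and 0 for bile acids.

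Vehicle replicate 3, in which hepatocyte markers were low, was also low in these lists. Without it Abcc2 lay at 1.56, Fads2 at 1.93 and Cyp1b1 at -2.39. Ces2c lay at -2.53 without vehicle replicate 2, and Nr1i3 at 2.41 without vehicle replicate 1. Without vehicle replicate 3 the medians were 0.68 for fatty acid oxidation, 0.60 for cholesterol synthesis, 0.87 for bile acids, 0.34 for lipogenesis and 0.65 for cytochromes P450. Camera still called each of the 5 lists higher. Without vehicle replicate 2 or any one ginkgetin replicate, the count over the list alone was 0 for cholesterol synthesis and 0 or 1 for bile acids and fatty acid oxidation. It was 0 for lipogenesis without vehicle replicate 2 or ginkgetin replicate 2 or 3, and 2 for cytochromes P450 without vehicle replicate 3. Without vehicle replicate 1 it was 12 for cholesterol synthesis, 14 for bile acids, 20 for fatty acid oxidation, 22 for cytochromes P450 and 5 for lipogenesis. With equal library totals, which moved the median of all genes to -0.53, the medians were 0.66 for hepatocyte markers, 0.37 for cholesterol synthesis, 0.49 for lipogenesis and 0.83 to 0.93 for the other 3 lists. All 6 of these lists were still called higher. That scaling moves nearly all genes of a library alike and camera compares a list with the other genes, so these calls say little about scaling.

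Genes of ER stress and the integrated stress response rose as a list (17 of 20 higher, median 0.59, camera adjusted p = 0.00063, and adjusted p = 0.51 with an estimated correlation), led by Trib3 (1.67), a pseudokinase induced by that response. Trib3 was the 1 member past over the list alone, against 0 over all genes. That count was 5 without ginkgetin replicate 1, 2 without vehicle replicate 3 and 0 without vehicle replicate 2 or ginkgetin replicate 2 or 3. Mitochondrial respiratory chain genes rose as a list by a smaller amount (28 of 28 higher, median 0.43, camera adjusted p = 3.6e-05, and adjusted p = 0.51 with an estimated correlation), led by Uqcrc2 (0.99), with 0 members past over the list alone. Both calls were lost with quantile scaling (adjusted p = 0.17 and 0.42). With equal library totals the medians were 0.07 for the stress genes and -0.07 for the respiratory chain, the latter below 0 but above the -0.53 of all genes.

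The other lists were not called. Acute phase genes had a median of 0.42 (camera adjusted p = 0.27), with Hamp the 1 member past over the list alone, and were called with equal library totals (adjusted p = 0.014). With 1 library left out their median ran from -0.05, without vehicle replicate 3, to 0.91, without vehicle replicate 2 (adjusted p = 0.052), and the count was 1 or 2. Of the 20 acute phase genes tested, 13 were higher and 7 lower. Crp (2.35) was higher, Lbp (-1.31) and Lcn2 (-3.74) were lower, and none of them passed. Lcn2 had 21.4, 2190 and 1458 normalized reads with vehicle and 113, 18.5 and 12.4 with ginkgetin. Antioxidant and NRF2 targets had a median of 0.18 and a mean of -0.27 (camera adjusted p = 0.40, direction higher). Gclm (1.23), a subunit of the glutathione synthesis enzyme, was higher and Gpx2 (-4.81), a glutathione peroxidase, was lower, both past over the list alone. That count was 0 without vehicle replicate 2 or ginkgetin replicate 2, 1 without ginkgetin replicate 3 and 3 without vehicle replicate 1. With 1 library left out the median ran from 0.19 to 0.30 and Gpx2 from -6.02 to -3.91. Gpx2 had 17.7, 0 and 1.24 normalized reads with ginkgetin, so the size of its change depends on the 1 added before taking logs. Nqo1 (-1.64, SE 0.481) was lower and Txnrd1 (0.72, SE 0.274) higher, and neither passed over the list alone. Interferon-stimulated genes had a median of -0.19 (adjusted p = 0.51, and 0.015 without vehicle replicate 3), from -0.38 to -0.01 with 1 library left out. Circadian clock genes had a median of 0.11 and a mean of -0.26 (adjusted p = 0.99, direction lower), and immediate early genes a median of -0.45 (adjusted p = 0.48). With 1 library left out these medians ran from -0.22 to 0.33 and from -0.75 to -0.01. Both had 0 members past over the list alone, against 3 clock genes without ginkgetin replicate 3 and 2 immediate early genes without vehicle replicate 1. Of the clock genes 10 were higher and 8 lower, so a test for 1 direction cannot exclude a clock difference. For change in either direction fry gave an adjusted p of 0.31. The smallest p values belonged to Dbp (-2.16), Per3 (-2.07), Bhlhe41 (-2.65) and Per2 (-1.22), all lower. Of these, Dbp, Per3 and Per2 overlapped between groups. Erythroid markers had a median of 0.44 and a mean of -0.22 (adjusted p = 0.61, direction higher), with Epb42 (-2.84) past over the list alone. That count was 0 without vehicle replicate 2 or ginkgetin replicate 1 or 3, and the median ran from 0.09 to 0.62 with 1 library left out. Pancreas, fat and muscle markers had a median of 0.00 and a mean of 0.54 (adjusted p = 0.26, and 0.035 with quantile scaling and 0.023 with equal library totals), with Cela1 (2.0) and Cpb1 (3.39) past over the list alone. With 1 library left out the median ran from -0.16 to 0.24 and Cpb1 from 2.72 to 4.34, and the count was 1 or 2. The highest member in vehicle replicate 3 was Cela1 at 227 normalized reads.

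**Figure D3:**
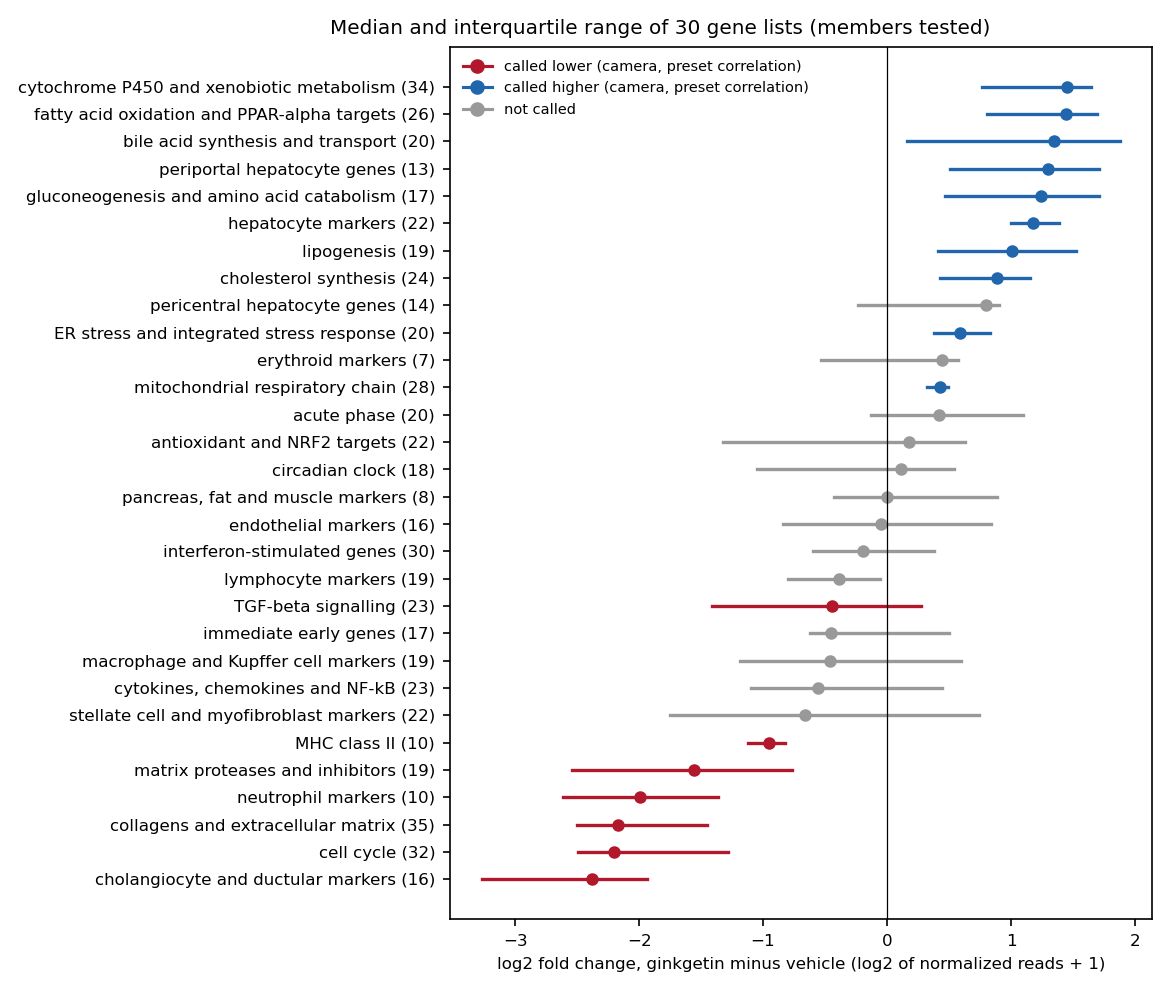
Median log2 fold change (points) and interquartile range (lines) of the tested members of 30 gene lists, ginkgetin minus vehicle, with the number of members in parentheses. Camera with the preset correlation called 7 lists lower, in red, and 10 higher, in blue, and with an estimated correlation it called 0.

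In all, camera with the preset correlation called 17 of the 30 lists, and 0 with a correlation estimated per list, where the smallest adjusted p was 0.51. Some lists share members, so their calls are not independent. Hal, Sds, Gls2 and Pck1 are in both the periportal list and that of gluconeogenesis and amino acid catabolism. The estimated correlation was 0.67 for the matrix list and 0.91 for hepatocyte markers. In 11 lists the mean levels of the 3 vehicle libraries and the 3 ginkgetin libraries did not overlap, each with an exact permutation p of 0.1, the smallest possible. The pancreas, fat and muscle list was among the 11 and was not called. Of the called lists, hepatocyte markers, cytochromes P450, lipogenesis, ER stress and MHC class II overlapped between groups, at an exact permutation p of 0.2. Periportal genes and gluconeogenesis and amino acid catabolism also overlapped, at 0.3.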

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

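Tests on recovered reads, equal library totals and the threshold of 0.10 were chosen after the result was seen. The 2 genes past the threshold (limma) stayed 2 with other pseudocounts and filters, TMM scaling, a 2-fold threshold or non-robust moderation, became 1 with quantile scaling, and ranged from 0 to 696 with 1 library left out, where 1745 to 4123 genes had an unadjusted p under 0.05. Sample weights, whose estimation stopped before converging, gave 5957 genes, an unadjusted p 2963, a threshold of 0.10 gave 336 and equal totals 94 (10 higher, 84 lower). On recovered reads edgeR gave 0 with TMM, RLE or upper-quartile factors and with 50 reads in 3 libraries (2469, 2477, 2546 and 1780 unadjusted), and 6 without a filter, limma-voom gave 0 (2240 unadjusted), voom with weights 2421, and DESeq2 1339 (264 higher, 1075 lower, 2257 without an adjusted p). The cause of these gaps was not tested. Of genes at an unadjusted p of 0.05, 65.4% were lower, against 89.4% with equal totals, 78.6% with upper-quartile factors, 55.6% with quantile scaling and 56.2% with sample weights. The replicate block gave 0 genes (2382 unadjusted). Deviations of same-numbered libraries correlated at -0.16, 0.03 and -0.21. No pairing by replicate number was seen, but 3 such correlations cannot exclude it. Over the lists, camera called 14 to 20 of 30 in every setting with a preset correlation (17 in the report), 0 with an estimated correlation, and 0 with the block and an estimated correlation. Fry called 0 for 1 direction, 0 with the block, and 5 for change in either direction. Of 3069 values of 131 named genes under alternatives, 2651 kept their side of the threshold and direction, 392 newly passed (74 with DESeq2, 55 without vehicle replicate 1), 21 no longer passed and 5 reversed: Hba-a2 (-0.05) and Cela2a (0.11) with quantile scaling, Cel (-0.09) with sample weights, and Acta2, from -1.19 to 0.83 with 1 library left out, without vehicle replicate 3 and ginkgetin replicate 3. Cd276 passed in 13 of 24 alternatives (adjusted p 4.02e-15 to 0.259) and LOC367746 in 14 (3.98e-11 to 0.212). In simulated reads of this depth and spread, 6% of changes of 1 log2 unit and 71% of 2 were found. The changed genes all had means above the median, and no library was simulated to stand apart as vehicle replicate 3 does. These shares therefore do not describe power for other genes or for these libraries.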

Other observations

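The 3 gene groups of the next 2 paragraphs (mast cell genes, cell cycle inhibitors, and growth hormone-responsive and male-biased genes), and the tests on Cyp2c11 and on the size factors, were chosen after the result was seen. The counts of these groups describe genes picked for their values and are no test.

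Of 8 mast cell genes, 6 were lower with ginkgetin at an unadjusted limma p under 0.05 and 0 passed the adjusted threshold, at a median of -3.55 for the 8. Kit (-0.41, SE 0.29) and Hdc (-0.17, SE 0.84) were not among the 6, and the mean of Hdc was 76.2 normalized reads with vehicle and 79.9 with ginkgetin. The tryptase Tpsab1 had 58.1, 53.2 and 73.0 normalized reads with vehicle and 4.42, 0 and 0 with ginkgetin, and the chymase Cma1 had 133, 130 and 159 against 27.6, 9.26 and 0. The median ran from -4.58 to -2.65 with 1 library left out. Among inhibitors of cyclin-dependent kinases, Cdkn2a was at 14.2, 35.8 and 64.5 normalized reads with vehicle and 0 with ginkgetin, at least 10.9-fold lower. Cdkn2b was at -2.97 (SE 0.55) and Cdkn2c at -2.90 (SE 0.40), whereas Cdkn1a, the p21 inhibitor, was at 0.48 (SE 0.35), and Gdf15, a stress cytokine counted in this group, at -0.33 (SE 0.31). Of these 5 genes 0 passed the adjusted threshold, against 3 without vehicle replicate 1 and 2 without vehicle replicate 3 or with equal library totals.

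Of 11 growth hormone-responsive and male-biased liver genes, picked after their values were seen, 9 were higher with ginkgetin at an unadjusted limma p under 0.05 and 0 passed the adjusted threshold, at a median of 2.35 for the 11. Without vehicle replicate 3 the median was 1.66 with 6 at that p, and without vehicle replicate 1 it was 3.13 with 7 past the adjusted threshold. Socs2 (3.46, SE 0.68), a feedback inhibitor of growth hormone signalling, Igf1 (1.58, SE 0.44) and Mup4 (6.05, SE 0.80), a urinary protein, were among them. Socs2 was at 209, 31.6 and 63.2 normalized reads with vehicle and at 857, 1483 and 454 with ginkgetin. Mup4 was at 4.75, 0 and 0 with vehicle and at 101, 89.1 and 181 with ginkgetin. The size of its change therefore depends on the 1 added before taking logs.

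Cyp2c11, the main cytochrome P450 of the male rat liver, was at 24.1 and 165 normalized reads in vehicle replicates 2 and 3, against 7962 in vehicle replicate 1 and 11515 to 20727 in the ginkgetin libraries. Mup5, a urinary protein gene outside that family, was at 4916, 2.50 and 208 in vehicle replicates 1 to 3. Female animals in the vehicle group are argued against, since the lower ratio of Y-linked Kdm5d to the mean of the other 4 libraries was 0.67. A lower share of hepatocytes in vehicle replicate 2 is argued against as the whole cause, since Cyp2c11 lay at -8.31 relative to vehicle replicate 1 while hepatocyte markers lay between -1.12 and 0.60. A candidate explanation, not tested here, is weaker growth hormone signalling in those livers. Other differences between these libraries were not tested as causes either. The acute phase gene Lcn2 was at 21.4, 2190 and 1458 normalized reads in vehicle replicates 1 to 3, and at 113, 18.5 and 12.4 with ginkgetin. Lbp, of the same list, did not follow that order, at 4605, 10774 and 3549 in vehicle replicates 1 to 3. Severity of disease stays open, as do reads shared within the Cyp2c family. Treatment does not separate these 3 vehicle libraries.

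Vehicle replicate 3 had more matrix and fewer hepatocyte transcripts than the other vehicle libraries. A lower hepatocyte share alone is argued against for this library, since the medians of 6 other cell type lists spread over 1.85 log2 units. They ran from 0.11 for lymphocyte to 1.96 for stellate cell markers, with bootstrap 95% intervals over genes of -1.80 to 0.52 and 1.17 to 3.03. These intervals describe a single library and do not measure spread between samples. Tissue of another organ is argued against for pancreas, fat and muscle, since 0 of their markers reached 100 normalized reads and over 4-fold the other vehicle libraries. A piece of liver with more scar, or an animal with more advanced fibrosis, may account for the difference, and neither of these was tested.

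Matrix genes were lower with ginkgetin. Vehicle replicate 3 as the only cause is argued against, since the matrix list kept a median of -1.27 without it. The list's mean level was -0.11 and 0.48 in vehicle replicates 1 and 2, above -0.60, -0.85 and -1.65 with ginkgetin. The bootstrap 95% interval of the median, -1.59 to -1.02, resamples genes and does not measure spread between samples. The size factors as the only cause are argued against too. With quantile scaling in their place the list lay at -2.16 (bootstrap 95% interval over genes -2.44 to -1.35). That scaling moved hepatocyte markers from 1.18 to 0.59. An effect of ginkgetin and a difference in disease severity between the groups that preceded treatment both stay open, untested.

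The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real grouping gave 2 genes past the limma threshold and 2963 at an unadjusted p of 0.05, the highest of the other splits gave 0 and 1388, and so 1 split, the real one, gave as many for each count. For gene lists called by camera with the preset correlation, the real grouping gave 17 and the highest other split 19, and 4 of the 10 splits, the real one included, gave as many.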
